A study of Mus musculus with 8 samples.

How the data were processed

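RNA of sorted mouse CD4+GFP+ regulatory T cells was measured on 8 Illumina MouseRef-8 v2.0 bead arrays with 1 colour, 4 labelled as treated with G-CSF and 4 with saline. Groups and replicate numbers were taken from the treatment labels and titles. The titles and intensity columns of the 4 controls say naive where their treatment label says saline, so they may have been untreated. No label says that the samples of a group came from separate mice or sorts, so the p-values measure the spread between these samples, which may be technical. The labels and file headers name no slide, scan day or batch.

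The deposited table holds non-normalised probe intensities for 25697 probes on each array, with a detection p-value per probe and array, per the file headers. GenomeStudio is named in the submitters' processing notes, without a version. The lowest intensities lay between 70.3 and 82.3, so no background had been subtracted from the deposited intensities. A second deposited table holds log2 values of the same arrays, and its steps are not given in the sources used here. Recomputing it showed log2 of the intensities, quantile normalised over the 8 arrays, with each probe centred on its median. The recomputed and deposited log2 values of an array differed by a standard deviation of at most 1.109e-04, and no array's values correlated above 0.745 with those of another array. Direction and scale of that table are therefore those of the intensities, and only its centring removes the level of a probe.

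The deposited intensities and detection p-values disagree about the groups. The p-value columns name no sample and each stands beside 1 intensity column. Within an array a detection p-value can only fall as the intensity rises. For 0 of the 8 arrays did the p-values beside the intensities do so, with 13.1% to 26.1% of the intensity steps against the order (tolerance 0.0001). Each of the 8 intensity columns was in perfect order with exactly 1 p-value column, that standing beside the same replicate number of the other group. Either the p-value columns or the intensity columns were placed under the wrong group. The log2 table carries the same labels as the intensities but may have been made from them, so it does not settle which. Here the labels of the intensity columns were kept. Every direction given as higher or lower in arrays labelled G-CSF turns if the intensity columns are the ones out of place. Each p-value column was joined to the intensities that it fits. This join rests on the values, because no header gives it. It was made after a first fit with the columns as placed, it sets no sample's group, and the columns as placed were kept as an alternative.

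Intensities were background-corrected with normexp from the detection p-values, quantile normalised and put on the log2 scale with an offset of 16 (neqc in limma 3.58.1, R 4.3.3). Probes were kept with a detection p-value under 0.01 on at least 4 of the 8 arrays, whatever the group, which left 10205 probes. This filter does not depend on how the p-value columns are joined. The test was limma's lmFit and eBayes on the 4 arrays of each label, adjusted by Benjamini-Hochberg over the 10205 probes and called at an adjusted p under 0.05. In the lists and the fixed set, a gene's probe was the brightest kept probe. Among the largest rises and falls it was the brightest called probe, which can be dimmer than a probe of the gene that was not called. A gene with no kept probe is given as not well above background. Where a probe was below background on all arrays of a group, its fold is a lower bound, against the mean over that group's arrays of the higher of the lowest intensity above background and the probe's own. Of the probes, 23978 were listed with 1 gene symbol, 0 with several and 1719 were unnamed here. Of the named probes, 23962 were matched to RefSeq's GRCm38.p6 table by Entrez identifier and 16 were not, with 0 symbols changed. The files name no genome build, so no coordinates are given.

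There were 25 gene lists (17 of T cell biology and 8 of cell type markers), tested with camera at a preset inter-gene correlation of 0.01 where at least 3 members were measured, which held for 22. Estimated correlation and fry were alternatives. Named genes follow a rule. It takes the 12 largest rises and 12 largest falls among called probes whose groups do not overlap, up to 4 called members of each list, or the 2 with the smallest p where none was called, and a fixed set around G-CSF, IL-10 and helper T cell lineages, of which one gene is not reported here. Groups, tests, lists, the rule and most alternatives were fixed before the data were examined. The alternatives were other background corrections, median scaling, the deposited log2 table, other filters on dim probes, other variance models, array weights, the replicate number as a block, each array left out, a size threshold, limma's treat and other list tests. Alternatives chosen after seeing the data were median scaling over the probes detected on all 8 arrays, the 2 brightest arrays left out, array brightness as a covariate, and the p-value columns as placed. The planned median scaling set no subset of probes and was run over all of them. The version over detected probes was added once the planned one had been seen to call mostly rises.

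The fit was tested on simulated data with the spread of each of the 10205 probes and 200 probes changed. It called 7.46% of probes changed by 0.5 on the log2 scale, 67.2% of those changed by 1 and 97.0% of those changed by 2, all with the right sign, and 8 unchanged probes. Of 20 simulated lists of 20 members it called the 1 that was shifted and 0 of the others. The simulated probes were drawn independently, so this does not show how the list test behaves where genes vary together. The number of arrays limits the precision. Figures and the column check used Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.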

Results

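G-CSF is a growth factor that mobilises stem cells from the bone marrow, and the series asks whether it acts on T cells directly and through IL-10. The samples were regulatory T cells, sorted as CD4+GFP+ from C57BL/6 mice carrying a FoxP3-GFP reporter. There were 4 arrays labelled G-CSF and 4 labelled saline, whose titles call them naive. Between 9588 and 10519 of 25697 probes were detected on an array. The intensities and detection p-values of the deposited table disagree about which group is which, so every higher or lower below is for arrays by the label of their intensities and would turn if those labels are the ones out of place.

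Regulatory T cell RNA was detected at similar breadth in both groups, but the arrays differed in brightness. Arrays labelled G-CSF had 10251 ± 239 detected probes (SD, n = 4) and those labelled saline 10026 ± 420 (SD, n = 4; 2-sided exact permutation p = 0.40). Median raw intensity was 144.2 ± 26.0 (SD, n = 4) against 122.0 ± 2.99 (SD, n = 4), with an exact permutation p of 0.0286, the smallest that 4 against 4 allows, and an adjusted p of 0.05 over 7 array measures. The difference came mostly from G-CSF replicate 3 (180.8) and replicate 4 (145), while the other 6 arrays lay between 117.8 and 125.8. The first principal component held 46.1% of the variance and separated the labels (exact permutation p = 0.0286, adjusted p = 0.05), with the 2 brightest arrays at one end at 33.0 and 37.1. The separation was narrow, with G-CSF replicate 1 at -2.57 and saline replicate 1 at -6.57. G-CSF replicate 1 correlated at 0.989 with G-CSF replicate 2. With G-CSF replicates 3 and 4 it correlated at 0.969 and 0.971, below its 0.977 to 0.983 with the saline arrays. Pairs of arrays correlated across probes at 0.967 to 0.991 within G-CSF, 0.963 to 0.993 within saline and 0.947 to 0.983 between them, so no array was a copy of another.

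**Figure D1:**
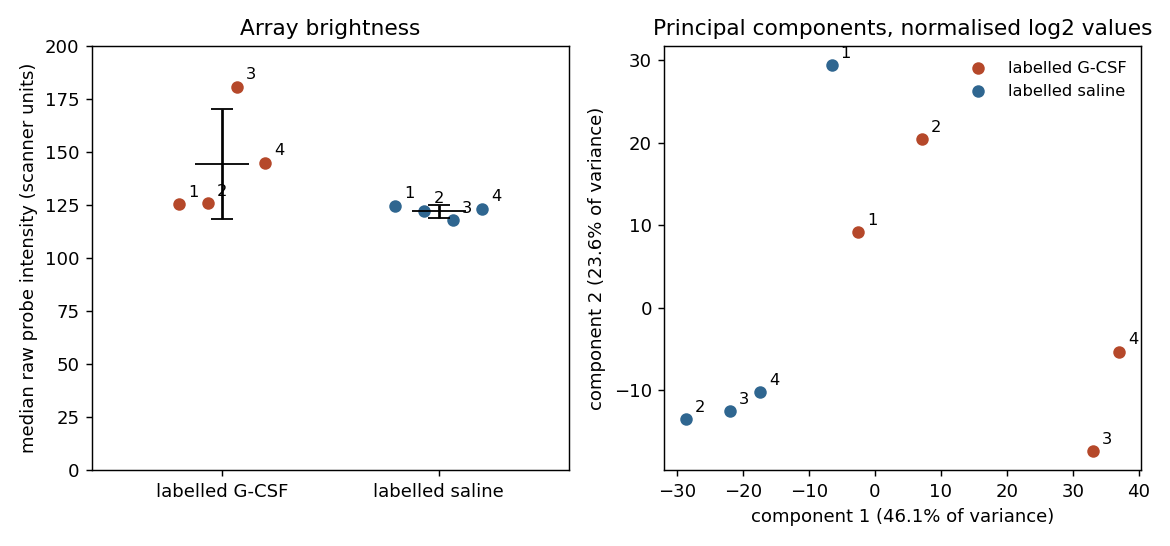
Left, the median raw probe intensity of each array (points, numbered by replicate) with the mean and SD of 4 arrays per label. Right, components 1 and 2 of the normalised log2 values, where labelled G-CSF replicates 3 and 4 lie at 33.0 and 37.1 on component 1. Group names are the labels of the intensities, which the detection p-values contradict.

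Il10, the gene of the suppressive cytokine IL-10, was among the largest falls in arrays labelled G-CSF, by 1.46 ± 0.20 on the log2 scale (SE, n = 4 per group; limma adjusted p = 0.0253). Falls were also found for Sik1 (-1.71), a kinase gene induced by cAMP, Coq10b (-1.60 on 1 of 2 probes, -0.52 on the other), the RNA helicase gene Ddx5 (-1.53), the repressor gene Tgif1 (-1.46 on 1 of 3 probes, -0.55 on the brightest, adjusted p = 0.182), and Atf4 (-1.34), a transcription factor of the stress response. Sik1 was well above background on only 2 of the 4 arrays labelled G-CSF, so the size of its fall is uncertain. Zscan2, a zinc finger gene, was at least 2.10-fold higher in arrays labelled G-CSF, since it was not well above background on any array labelled saline. Rises included the mitotic kinesin gene Kif18b (1.40, and 1.42 on a brighter probe that was not called), B4galnt4 (1.24), Sipa1 (1.15) and Tbx21 (1.14), the gene of the Th1 regulator T-bet. On arrays labelled saline, the called Kif18b probe was well above background on 1 of 4 and B4galnt4 on 3 of 4. In all, 224 probes of 10205 were called, 97 higher and 127 lower, which are 89 and 111 genes.

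These names come from the rule's 12 largest changes each way. The other falls were Klf6 (-1.36, on 1 of its 2 probes), Hsd11b1 (-1.31), Rgcc (-1.27), Zfp386 (-1.27), Igfbp4 (-1.26) and Insig1 (-1.24), an inhibitor of sterol synthesis. Hsd11b1 has 4 probes and only 1 was called, the others lying between -0.10 and 0.09. The other rises were Ttyh3 (1.14) and Pacsin1 (1.12 on 1 of 2 probes, 0.24 on the brighter). On arrays labelled saline, the called Pacsin1 probe was well above background on 2 of 4. A further 5 rises were of genes not well above background on any array labelled saline. These were Foxp4 (at least 1.71-fold), Scmh1 (1.5), Nr2c1 (1.27), Dnase1l2 (1.24) and the spindle gene Aspm (1.10). By the rule, the groups of these genes do not overlap. Of all probes tested, 13.6% had groups that did not overlap, against 2.86% by chance on average over splits. Where probes vary together, a single split can lie far above that average without any effect of treatment. Median raw intensity also did not overlap between the labels, so this share does not tell treatment from brightness. Called changes as fitted ranged from 0.57 to 2.04 in size on the log2 scale, with a median of 0.88. The largest is that of Zscan2, 1 of 12 called probes below background on every array of a group, whose fitted sizes are uncertain.

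**Figure D2:**
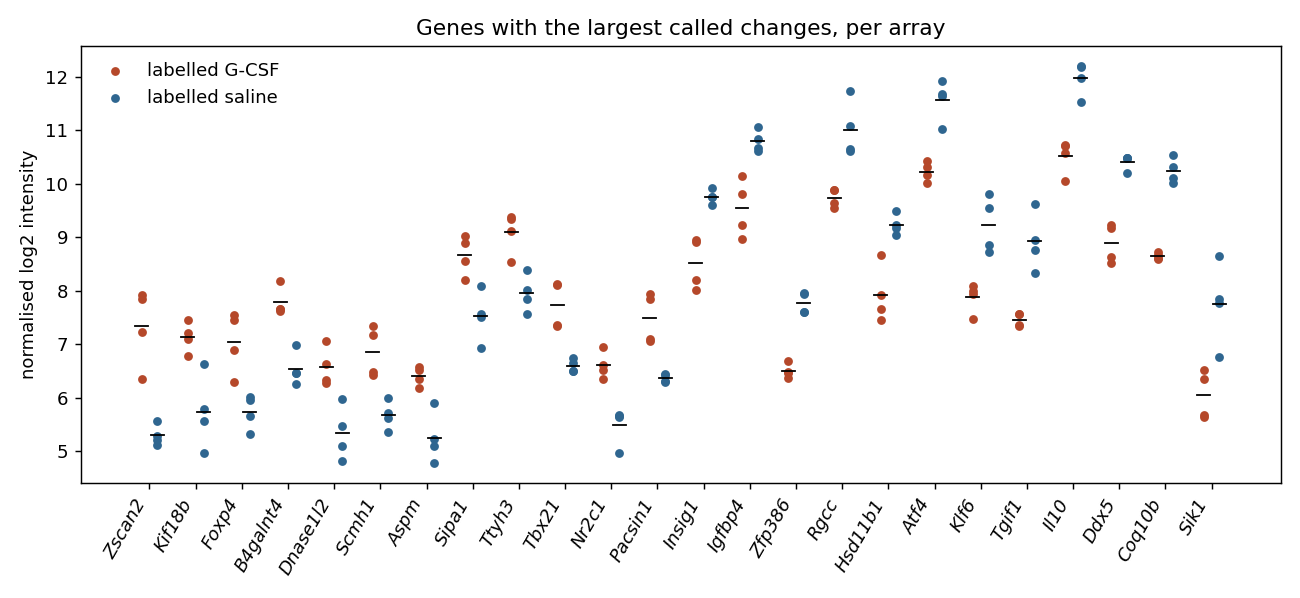
Normalised log2 intensity (vertical axis) of the 12 genes with the largest rises and the 12 with the largest falls, 1 point per array and a bar at the mean of 4 arrays. By the rule that chose these genes, the 4 arrays labelled G-CSF lie wholly above or below the 4 labelled saline, as for Il10 (mean 10.51 against 11.97). Group names are the labels of the intensities, so directions would turn if these are out of place.

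The number of calls depended on single arrays. It became 712 without G-CSF replicate 1, 1 without replicate 2, 4 without replicate 3 and 1 without replicate 4, and 1089, 10, 1 and 1 without saline replicates 1 to 4, and limma called 0 with the 2 brightest arrays left out (1439 probes at an unadjusted p under 0.05 against 2537 with all 8). The count at an unadjusted p under 0.05 moved less, from 1599 without G-CSF replicate 4 to 3068 without saline replicate 1. Without G-CSF replicate 2 it was 2605. The 224 called probes were picked on all 8 arrays. With one array left out, each kept an unadjusted limma p of 0.0051 or less. They had a median size of 0.83 to 0.95 with one array left out and 0.78 (quartiles 0.64 and 0.92) without the 2 brightest, against 0.88 (quartiles 0.78 and 1.04) with all 8. Median scaling in place of quantile normalisation gave 810 higher and 46 lower, against 97 and 127, with a median shift over all probes of 0.29. Median scaling over the detected probes, chosen after seeing the data, gave 76 higher and 173 lower.

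Genes of regulatory T cell identity were not called as a group. Of the 20 measured members, 0 were called (3 higher and 2 lower adjusted over the list alone), and the list had a camera adjusted p of 0.804. Foxp3, the lineage regulator, had a log2 change of 0.49 ± 0.30 (SE, n = 4 per group; limma adjusted p = 0.323) on the brightest of 3 probes and 0.79 and 0.97 on the others (adjusted p = 0.148 and 0.122). Dusp4 had -1.11 (adjusted p = 0.0829) and Ikzf4 0.83 (adjusted p = 0.0720). Ctla4, an inhibitory receptor, had -0.57 (adjusted p = 0.0951), and Il2ra, the IL-2 receptor alpha chain, 0.21 (adjusted p = 0.458). Of 21 effector Treg genes, Il10 alone was called, as a fall, and 14 had a negative change (adjusted p of the list 0.240, under 0.05 in 3 of 24 alternatives, 1 higher and 4 lower over the list alone). Il10 was also the 1 called gene among 15 suppressor molecules, of which 9 had a negative change (adjusted p of the list 0.804, 4 and 2 over the list alone). Among 14 resting T cell genes, Igfbp4 alone was called, as a fall (adjusted p of the list 0.831, 2 and 2 over the list alone).

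On the axis of G-CSF and IL-10, Il10 was the only called gene of 13 measured (adjusted p of the list 0.831, 3 higher and 1 lower over the list alone). The receptor genes had values of 0.60 for Il10ra (limma adjusted p = 0.0589) and -0.04 for Il10rb (0.883). Csf3r, which encodes the G-CSF receptor, has 5 probes, and none was detected on any array. Tgfb1 had 0.87 (adjusted p = 0.0554). In the STAT3 and cytokine feedback list 2 of 21 genes were called, both as rises, with an adjusted p of 0.831 for the list (2 and 2 over the list alone). These were Bcl6 (0.86), a repressor that directs follicular T cell identity, and Bcl3 (0.73). Socs3 had -0.31 and Stat3 0.19 (adjusted p = 0.455 and 0.513).

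Among helper lineage genes, Tbx21 was the 1 gene called on its brightest probe, a rise, of 10 measured in the Th1 list (adjusted p of the list 0.831, 1 and 1 over the list alone). Ifng, the interferon gamma gene of that list, had -0.75 on its brightest probe (limma adjusted p = 0.0966). A dimmer probe of Ifng was called as a fall, given under the other observations and picked after its values were seen. Of 7 measured Th2 genes 0 were called (adjusted p = 0.318, 0 over the list alone), with Ccr4 at -0.56, Il17rb at -0.43 and Gata3, the Th2 regulator, at -0.03. Of 7 Th17 genes 0 were called (adjusted p = 0.753, 1 higher over the list alone), with Irf4 at 0.35. Il4 and the integrin gene Itga4 were not well above background, and Itgb7 had 0.23.

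Cell cycle and interferon genes had the smallest p among the lists with a positive shift, without passing the test, although each passed under some alternatives (8 of 24 for cell cycle and 9 for interferon). Tk1, a thymidine kinase of DNA synthesis, was the 1 called of 24 cell cycle genes (0.84, limma adjusted p = 0.0477), and 20 of 24 had a positive change. Oasl1 was the 1 called of 26 interferon response genes (0.90), and 6 were higher adjusted over the list alone. Both lists had a camera adjusted p of 0.0620. Immediate early and TCR signal genes had the smallest p among those with a negative shift, with 13 of 19 negative and 0 called (adjusted p = 0.0755, under 0.05 in 8 of 24 alternatives, 1 and 1 over the list alone), among them Klf6 at -0.76 on its brightest probe and Egr2 at 0.55. In the other lists, Atf4 was the 1 called gene, a fall, of 17 stress and unfolded protein genes (list adjusted p = 0.571). Cxcr5, a B cell follicle homing receptor, was the 1 called rise of 17 homing genes (0.97 on 1 of 3 probes, list adjusted p = 0.571). Tnfrsf1a was the 1 called rise of 14 apoptosis genes (0.99 on 1 of 3 probes, list adjusted p = 0.886, list median -0.02 and mean 0.04). The called Tnfrsf1a probe was well above background on 1 of 4 arrays labelled saline. Of 15 glycolysis genes and 12 glucocorticoid response genes 0 were called (adjusted p = 0.804 and 0.753), with Hk1 at 0.87, Slc2a1 at -0.53, Il7r at 1.12 on 1 of 2 probes (0.06 on the other) and Sgk1 at -0.84.

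**Figure D3:**
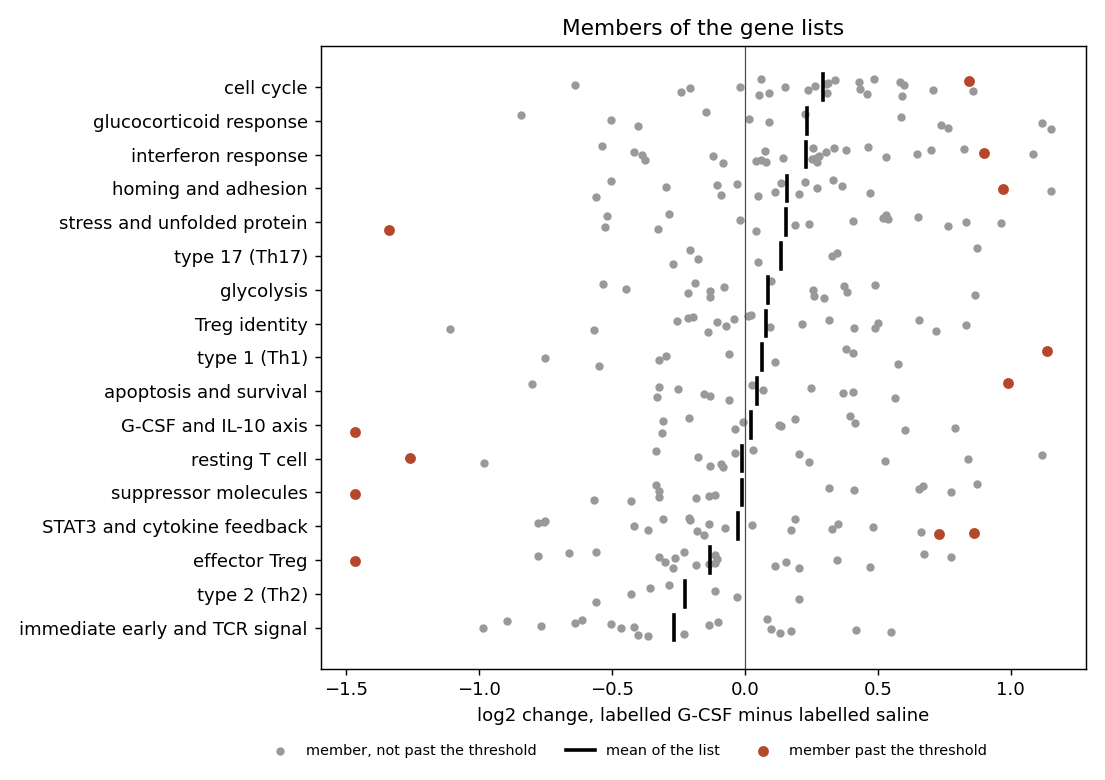
Log2 change (horizontal axis, labelled G-CSF minus labelled saline) of each measured member of the 17 biology lists, with the list mean as a bar and members past the threshold in red. Among these 17 lists cell cycle has the highest mean (0.29) and immediate early and TCR signal the lowest (-0.27), and 0 lists passed the list test. The sign would turn if the labels of the intensities are out of place.

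Markers of other cells were mostly not well above background, and none of their lists was called. Monocyte and macrophage genes were an exception, with 10 of 15 on the array measured. Some measured markers were bright, such as Cd8b1 (mean log2 intensity 11.25 in arrays labelled G-CSF, 11.57 in those labelled saline) and Cd79b (9.93 and 10.01). Of 21 neutrophil and precursor genes on the array, 17 were not well above background, and of the 4 measured Ltb4r1 fell (-0.78, limma adjusted p = 0.0471; list adjusted p = 0.318). Monocyte and macrophage genes had Ctss at 0.68 and C1qa at 0.59 among 10 measured (list adjusted p = 0.465). H2-Ab1 and H2-Eb1, class II genes of dendritic cells and B cells, both had -1.12 (adjusted p = 0.189 and 0.212), with -1.08, -1.30 and -1.91 on the other 3 probes of H2-Ab1 (the last with adjusted p = 0.0689) and an SD between saline arrays of 1.20 and 1.31 (n = 4, limma), among 6 dendritic cell genes (list adjusted p = 0.571). Cd8b1 had -0.33 on its brightest probe (0.12 on the other) and Nkg7 -0.34 among 5 CD8 and NK genes (adjusted p = 0.804), and Thy1 had 0.36 and Cd247 -0.64 on its brightest probe (0.14 and 0.02 on 2 others) among 12 T cell genes (adjusted p = 0.753). Too few genes were measured to test B cell (Fcmr -0.47, Cd79b -0.07), erythroid (Hbb-bt 1.01, Hba-a1 0.38) and progenitor lists (0 of 11 measured).

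Across the 22 lists tested, camera called 0, with 4 at an unadjusted p under 0.05 and a smallest adjusted p of 0.904 with an estimated correlation. Fry called 0 for a shift in 1 direction and 16 for change in either direction, neither of which compares a list with other genes.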

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

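Of these tests, those of Il10, of the detection p-values and of the sizes without the brightest arrays, and the split count for gene lists, were chosen only after the result was seen.

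A value far from the other 3 arrays of its group was found in 9 of 132 groups of 4 arrays, and chance gives about 1 in 20. In arrays labelled G-CSF these were replicate 4 for B4galnt4 (log2 intensity 8.18, others 7.62 to 7.66), C1qa (7.15, others 6.86 to 6.91) and Il10rb (9.67, others 9.98 to 9.99), replicate 1 for the haemoglobin gene Hba-a1 (10.34, others 8.85 to 9.08), and replicate 3 for Oasl1 (7.65, others 8.35 to 8.41). In arrays labelled saline they were replicate 1 for Ctla4 (14.67, others 14.00 to 14.09), replicate 2 for Ddx5 (10.20, others 10.48 to 10.49) and Thy1 (13.79, others 14.01 to 14.04), and replicate 3 for Nr2c1 (4.96, others 5.64 to 5.67).

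Only 1 of the 35 splits into 4 and 4, the real one, called as many as 224 probes, and the highest other split called 1. This argues against a chance division of the arrays but does not exclude it. A share of 1 in 35 is the smallest that these splits allow, and the number of calls depended on single arrays. At an unadjusted p under 0.05 the margin was small, 2537 probes against 2468 for the split that exchanges G-CSF replicate 1 with saline replicate 1. Without the 2 brightest arrays limma called 0, with 2 fewer arrays and a median size of the 224 changes of 0.78 (quartiles 0.64 and 0.92, median SE 0.19) against 0.88 (0.78 and 1.04, median SE 0.18), a share kept of 0.888; of 14 other splits with both arrays on one side, which mix the labels and so may hold part of the same difference, 13 kept less (lowest 0.552) and 1 kept 0.893, that which exchanges the replicates 1, so picking the probes on all 8 arrays could account for much of the share. Brighter arrays stay open in whole or in part: of 224 probes picked on the 2 brightest arrays and 2 saline arrays, 64.7% to 91.5% (median 82.1%) went the same way in the other 4 arrays over 6 choices, where a median of 60% or less was set beforehand as pointing to brightness and 75% in every choice as excluding it, and neither was met. An effect of G-CSF is the biological explanation that the design names.

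For gene lists there was no call to weigh against chance, since the real split called 0, which all 35 splits reach. The highest other called 10 and 27 called at least 1, which points to a structure of the arrays apart from the labels.

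The fall of Il10 in arrays labelled G-CSF was weighed against 3 explanations. Dilution by other cells would lower the Treg identity genes alike, and their median log2 change was 0.018 (SD 0.46 over 20 genes), which argues against it. These genes cannot address a shift between kinds of regulatory T cells, which was not tested. Array brightness as the whole cause is argued against by a change of -1.66 ± 0.24 (SE) without the 2 brightest arrays and -1.46 ± 0.20 with all 8. That argument is limited. In the 14 other splits with both arrays on one side, 59 of 291 picked probes over 1 in size were also larger without them. Over all probes limma's adjusted p of Il10 went from 0.0253 to 0.244 with 2 fewer arrays. Il10 was in the set fixed before any value was seen, and over that set's 12 measured genes limma's adjusted p was 0.00178. That p tests for a change and not against brightness. Weaker recent activation stays open, with the immediate early and TCR signal list lower at a camera adjusted p of 0.0755. An effect of the treatment stays open too, and its direction rests on the labels.

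For all 8 arrays the intensities fit the detection p-values placed beside the same replicate number of the other group. P-value columns out of place and exchanged intensity labels cannot be told apart, because both deposited tables carry the intensity labels and nothing independent ties an array to its treatment. If the intensity labels are the ones exchanged, 127 probes were higher and 97 lower with G-CSF, and Il10 was higher.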

How the results depend on the processing

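Median scaling over detected probes, the 2 brightest arrays left out, brightness as a covariate and the p-value columns as placed were chosen after seeing the data. Every called probe that an alternative tested kept its sign there, in all alternatives run. This was largely fixed in advance, since 222 of the 224 had groups that do not overlap. Leaving out arrays could not turn these, and changing only the filter or the variance model left the sizes as they were. The number of calls moved widely, and the cause was not tested except where stated. Against 97 higher and 127 lower (224), quantile normalisation of log2(intensity + 16) without background correction, of log2 with a floor of 10, and the deposited log2 table (series matrix value table) each called 58 higher and 99 lower, and they called 2, 2 and 1 gene lists against 0. Median scaling called 856 probes, 810 higher and 46 lower, and 1 list, with a median shift of 0.29, and over the probes detected on all arrays it called 249, 76 higher and 173 lower, and 2 lists, with a median shift of -0.06. No filter on detection called 4 probes, 0 higher and 4 lower, and 1 list, and detection p under 0.05 on at least 3 arrays called 14, 3 higher and 11 lower, and 1 list; both test more probes, most of them near background. Array weights called 3776 probes, 1880 higher and 1896 lower, and 1 list. With an absolute log2 change of at least 1 as well, 71 probes were called, 28 higher and 43 lower. With limma's treat against a log2 change of 0.5, 0 were called, 0 higher and 0 lower (249 at an unadjusted p under 0.05). With the 2 brightest arrays left out 0 were called, 0 higher and 0 lower, and 3 lists, and with log2 median raw intensity as covariate again 0, 0 higher and 0 lower, and 3 lists, the interferon response and the immediate early and TCR signal lists being among them in both. Fewer arrays or degrees of freedom entered these fits, and the median size of the 224 changes was 0.78 and 0.83, against 0.88. With the p-value columns as placed, 237 were called, 103 higher and 134 lower. Leaving out one array gave 1 to 1089 calls, 0 to 616 higher and 1 to 473 lower, and 0 to 5 lists. Fry, mixed, called 16 lists, and camera with an estimated correlation 0. The share of variance on the first component moved from 46.1% to 83.1% on unnormalised log2 intensities.

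With the replicate block (the replicate number as a block), 4 probes were called, 1 higher and 3 lower, and 0 lists. The deviations of same-numbered arrays correlated at -0.12 to 0.18, over 0.1 in 1 of 4 pairs, and 1 of 4 arrays labelled G-CSF correlated best with its own number. These values give no clear sign of pairing by number but are too few to exclude it, and the labels do not state it.

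Il10 had a log2 change of -1.66 to -1.19 over 22 alternatives and was called in 13. Of 671 values of called named genes under alternatives, 351 were no longer past the threshold and 0 reversed. The lack of reversals was largely fixed in advance, as for the called probes above. Signs changed 66 times, 13 times for named genes and 53 for list means, always between values not past the threshold. The slide as a block was not run, since the files name no slide. Low signal over background limits the called genes not detected in one group, whose folds are bounds. It also limits called genes detected on only some arrays of a group. Over the alternatives Sik1 ranged from -2.05 to -0.88, Kif18b from 0.59 to 1.79 and Pacsin1 from 0.58 to 1.38.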

Other observations

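Of these tests, that of sterol genes, and the splits and other settings for mitotic genes, were chosen after the result was seen, and every direction depends on the labels of the intensities.

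Several called genes outside the named set act in mitosis, among them Kif2c (1.06), Gtse1 (1.00 on 1 of 2 probes), Incenp (0.93) and Ckap5 (0.92), all higher in arrays labelled G-CSF and chosen after their values were seen. A hypothesis is that mitotic genes rose together. A list of other mitotic genes, written before their values were seen and with 0 called, had 22 of 24 measured members higher, with a mean log2 change of 0.48 and a camera adjusted p of 3.036e-05 over 3 lists. Chance cannot be excluded for that p, since 11 of the 35 splits of the arrays into 4 and 4 gave one as small (smallest other adjusted p 8.927e-16). A further limit is that 19 splits other than the real one passed the threshold. Some of these exchange only 1 array between the labels and so may hold part of the same difference. The split with the smallest p holds 2 arrays of each label on each side, which points to mitotic genes that vary together between arrays in part apart from the labels. The mean itself was highest in the real split (next 0.44), but the hypothesis came from mitotic genes called in that split. If mitotic genes vary together, this rank is not independent support. With an estimated correlation the camera adjusted p was 0.585, so a shared rise with the labels stays open. The mean lay between 0.32 and 0.59 with each array left out, and was 0.49 without the 2 brightest arrays and 0.46 with brightness as a covariate, but 0.78 under median scaling, which moved the median of all probes by 0.29, and 0.30 on the deposited log2 table. The adjusted p was 4.835e-04 and 5.627e-05 there. Sgo1 (1.07), Kif4 (1.03) and Pbk (0.92) had large values in that list, with adjusted p of 0.0702, 0.0774 and 0.0747 over all probes. A larger share of dividing cells is a possible explanation that was not measured here.

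Another hypothesis, that interferon-stimulated genes rose together, was not borne out in a list written before its values were seen. It had 19 of 31 members higher, a mean of 0.09 and an adjusted p of 0.466, so it does not extend the interferon response list of the report.

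A further hypothesis came from falls of Insig1 (-1.24), Sqle (-1.17 on 1 of 2 probes) and Nsdhl (-1.13, -1.09 and -0.89 on 3 of 4 probes), genes of sterol synthesis and its control. The 13 other sterol genes that were measured and not called had 8 lower, a mean of -0.02 and an adjusted p of 0.416, but 2 called falls had been left out of that list, so it says nothing about whether the fall is shared.

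Ifng, which encodes interferon gamma, was chosen after its values were seen. It was lower on both probes in arrays labelled G-CSF (-1.11, limma adjusted p = 0.0419, and -0.75, adjusted p = 0.0966), while Tbx21, which drives it in Th1 cells, was higher (1.14).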
